A study of Homo sapiens with 6 samples.

How the data were processed

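Bulk RNA sequencing libraries of CCD-18Co colonic fibroblasts treated with vehicle or with TWEAK at 50 ng/mL for 24 h were compared, with 3 libraries per group. Groups and replicate numbers were taken from the sample titles in the labels, and what the vehicle contained is not given in the sources used here. The labels' protocols state growth with 10% serum and a serum-free period of at least 6 h before treatment, and that libraries were prepared and sequenced at BGI. The submitters' processing notes name Trim Galore, STAR, Salmon, DESeq2 and the build GRCh38, with no versions, roles or order. The annotation, the strandedness of the library and any filter on genes are not given in the sources used here.

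The deposited values are a normalized expression signal per gene, named normalized counts in the authors' table, with 1 column per library and 18711 genes, none of them at 0 in every library. The values are not whole. Low values in each library cluster at a step of 0.969 to 1.05, which was taken as the value of about 1 read, but only 69.4% to 77.7% of low values lie within 0.1 of a whole multiple of that step. Whether factors per gene or fractional assignment of reads moved the other values was not tested. Whole reads were not recovered, and a test on counts was not used. Depth was estimated from the step at about 18400000 to 20000000 reads per library, and intervals and floors based on it cover counting error only. Since the table had been scaled by the authors before it was deposited, a change in total RNA per cell would not be visible in it.

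Of the gene symbols, 15828 matched a current symbol, 1216 an older one, and 1667 neither, in the gene tables used here. Coordinates come from the RefSeq table of the same build, GRCh38, and are 1-based. Ribosomal RNA genes, nuclear and mitochondrial, held 0.932% to 1.15% of the deposited total per library, and the 10 most abundant genes 9.78% to 11.4%.

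Values were transformed to log2(value + 1), and the 13518 genes with a mean of at least 10 over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (moderated test, prior variance with a trend over expression, group as the only term), with Benjamini-Hochberg adjustment. The other 5193 genes were not tested. Fold changes on this scale understate changes of low genes. Where a group held about 1 to 3 reads in all, the ratio is given with an exact binomial counting interval at 95%, and where a group was listed at 0, only the values are given. Summaries used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

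Before the data were examined, 34 gene lists were fixed, along with the design, the alternatives and the rule for named genes. Of these lists, 31 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Lists contained 6 genes that appear under older symbols. The rule named TNFRSF12A and TNFSF12, the 10 largest increases and 10 largest decreases in log2 fold change among genes called at an adjusted p of 0.05 with a mean of at least 50 and groups that do not overlap, and up to 4 called members of each list with the largest changes, or the 2 most abundant members of a list with none. Of the genes this rule named, 4 are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

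The procedure was tested on data simulated for TWEAK against vehicle with 13505 genes tested, over 10 simulations, each with 67 genes changed at each size. It recovered 77.0% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 94.7% of those changed 4-fold, and 6.62% of its calls were false. Far fewer genes were changed there than were called in the real data. The spread was smoothed over expression and no shift of a replicate was simulated, so these shares may differ in the real data. Camera called a list of 30 genes raised 1.3-fold in 10 of 10 simulations and a list of 30 unchanged genes in 0 of 10, where simulated genes were drawn independently, unlike real ones.

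Replicates of a group were compared in pairs by a chi-square value per gene, computed from the deposited values of genes with a mean of at least 10. The median chi-square per gene between replicates 1 and 2 was 0.935 in vehicle and 1.03 under TWEAK. In pairs with replicate 3 it was 2.39 to 2.75. These medians all lie above the 0.455 of pure counting noise, so the libraries were not pooled. Separate preparations of 1 culture would also exceed counting noise, so this does not show separate cultures. Alternatives fixed beforehand were other pseudocounts (0.5 and 5), no filter or a mean of at least 50, rescaling to the same total, recomputed size factors by the median of ratios, quantile normalization, no variance trend, the replicate number as a block, and each library left out in turn. Added after the data were seen were a fit without both libraries numbered 3 and a fit with each library's trends over GC content and transcript length removed, using the longest transcripts of GENCODE release 29 for the 12924 tested genes (95.6%) with a match. No column of the table was left unused.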

Results

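CCD-18Co cells, a commercially available line of human colonic fibroblasts, were grown in medium with 10% serum, kept without serum for at least 6 h, and then treated in serum-free medium for 24 h. Bulk RNA sequencing of total RNA gave 3 libraries from vehicle-treated cells and 3 libraries from cells treated with TWEAK at 50 ng/mL. TWEAK is a cytokine of the tumour necrosis factor family, encoded by TNFSF12, and its receptor Fn14 is encoded by TNFRSF12A. The table held 18711 genes, with deposited totals of 19150000 to 19540000 per library and 16213 to 16815 genes above 0. The step between low values put the depth at about 18400000 to 20000000 reads per library. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

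The comparison of TWEAK with vehicle addressed how this cytokine alters gene expression in colonic fibroblasts, in a series concerned with inflammatory fibroblasts and their contact with monocytes. Between TWEAK and vehicle, 3278 of 13518 tested genes differed at a Benjamini-Hochberg adjusted p under 0.05 (limma), 1761 higher and 1517 lower under TWEAK. With quantile normalization the balance turned, with 1598 higher and 1689 lower. The larger changes were mostly increases: 343 genes rose and 188 fell by at least 2-fold, and 115 rose and 8 fell by at least 4-fold. Of the called genes, 3270 had groups that did not overlap. Over all tested genes the groups did not overlap for 42.8%, where chance gives 10%. Leaving out any 1 library numbered 1 or 2 gave 2029 to 2245 called genes. Leaving out vehicle replicate 3 gave 3282 and TWEAK replicate 3 gave 3068. A call lost without a library numbered 1 or 2 therefore need not rest on that library alone.

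The first principal component held 53.6% of the variance and separated the treatments, and the second, with 19.8%, separated the replicate 3 libraries of both groups from the 4 others. Pearson correlations across genes, which are not independent replicates, were 0.981 to 0.990 between libraries of 1 group and 0.961 to 0.971 between groups. Leaving out both libraries numbered 3, a choice made after the data were seen, gave 5074 changed genes, of which 2688 rose and 2386 fell, and 3187 of the 3278 genes were again called in the same direction.

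**Figure D1:**
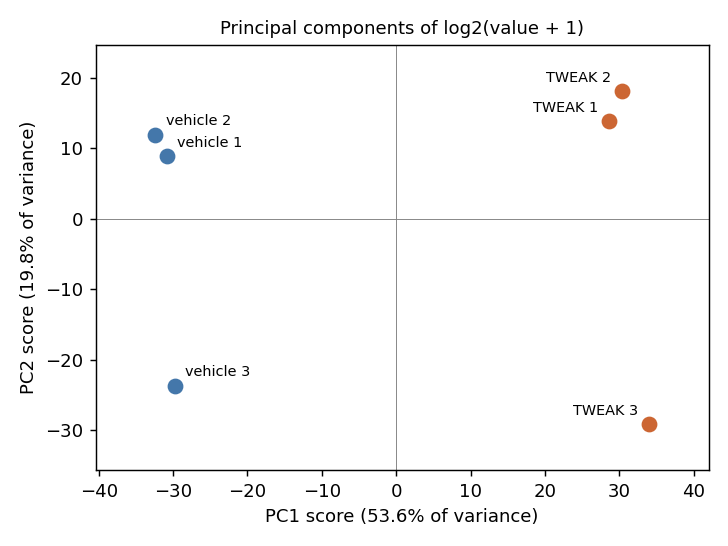
Scores of the 6 libraries on the first 2 principal components of log2(value + 1), with 1 point per library, blue for vehicle and orange for TWEAK. The x axis (53.6% of the variance) separates the groups, and the y axis (19.8%) sets replicate 3 of both groups apart.

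Both partners of the pathway changed. TNFRSF12A (chromosome 16, 3020368 to 3022383, GRCh38) rose from 894 ± 45.6 to 1309 ± 188 (deposited normalized value, mean ± SD, n = 3 per group). Its log2 fold change was 0.54 ± 0.10 (SE), with a limma adjusted p of 0.0066. TNFSF12 (chromosome 17, 7549058 to 7557881) fell from 423 ± 48.8 to 271 ± 9.34, with a log2 fold change of −0.64 ± 0.10 and a limma adjusted p of 0.0030. A readthrough locus with the neighbouring TNFSF13 shares sequence with TNFSF12, so the division of reads between them is uncertain. In what follows, log2 fold changes are on the log2(value + 1) scale with their SE, values are means ± SD with n = 3 per group, and every gene said to rise or fall passed the limma test.

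The 10 largest increases were taken among genes with a mean of at least 50 and groups that did not overlap. BIRC3 (chromosome 11, 102317484 to 102339403), an apoptosis inhibitor of the TNF receptor complex, rose from 13.5 ± 2.23 to 1666 ± 22.1, a log2 fold change of 6.85 ± 0.13. UBD (chromosome 6, 29555515 to 29559732), which encodes the ubiquitin-like modifier FAT10, was listed at 0.325 ± 0.563 in vehicle and 255 ± 26.7 under TWEAK. With about 1 read in all vehicle libraries together, its ratio was 768, with a counting interval of 137 to 30356 (95%, exact binomial), which covers counting error only. TAC3, the neurokinin B precursor, rose from 57.8 ± 27.5 to 2472 ± 327 (5.53 ± 0.35), and SLC7A2, an arginine transporter, rose from 436 ± 40.2 to 6124 ± 647 (3.81 ± 0.10). The lysosomal protease CTSS rose by 4.87 ± 0.27 and the acute-phase gene SAA1 by 5.64 ± 0.51, from only about 4 reads in vehicle. IL34 (4.92 ± 0.30) and IL32 (4.21 ± 0.13) rose, as did the natriuretic peptide gene NPPB (3.98 ± 0.43) and the ankyrin repeat gene ANKRD1 (3.80 ± 0.35). Adjusted p-values of these 10 genes ranged from 8.0e-08 for BIRC3 to 0.00044 for NPPB (limma).

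The largest decreases were smaller than the largest increases. The chemokine-scavenging receptor ACKR3 (chromosome 2, 236537122 to 236582354) fell from 2182 ± 109 to 645 ± 87.9, with a log2 fold change of −1.77 ± 0.10. RSPO2, which encodes a WNT-potentiating R-spondin, fell from 271 ± 71.0 to 78.6 ± 18.9 (−1.77 ± 0.22), and the complement gene C7 from 1530 ± 527 to 484 ± 160 (−1.65 ± 0.32). MARC1, now named MTARC1 (−1.88 ± 0.23), CORO2A (−1.83 ± 0.28), FAM180A (−1.70 ± 0.29) and FAXDC2 (−1.66 ± 0.20) also fell. Adjusted p-values of these 7 of the 10 largest decreases ranged from 1.7e-05 for ACKR3 to 0.0067 for C7 (limma).

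**Figure D2:**
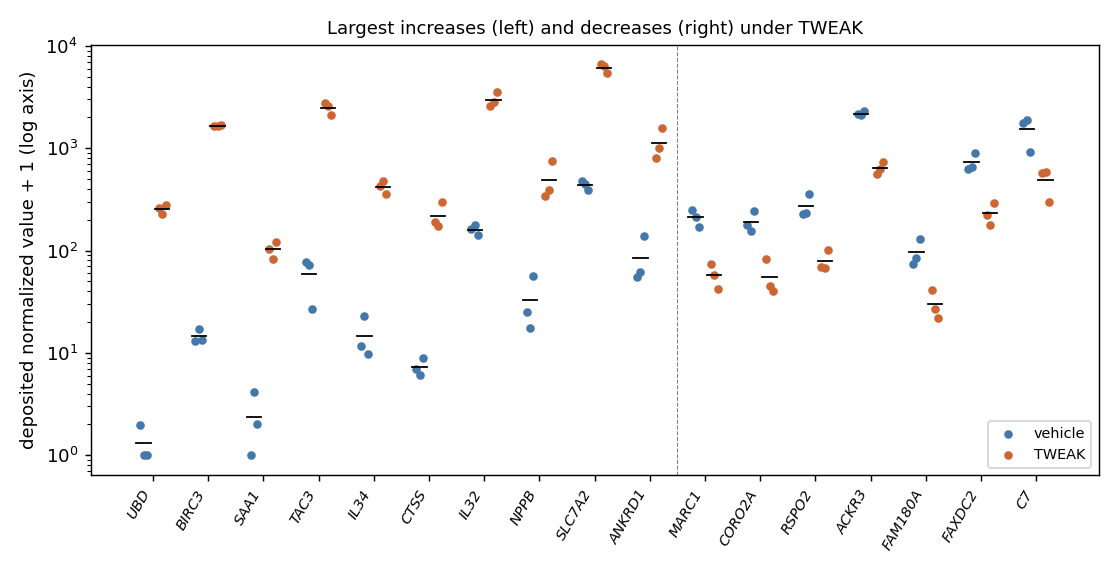
Deposited normalized values plus 1 (log axis) of the 10 largest increases and of 7 of the 10 largest decreases, with 1 point per library, blue for vehicle and orange for TWEAK, and a bar at the mean of each group. BIRC3 goes from 13.5 in vehicle to 1666 under TWEAK and ACKR3 from 2182 to 645, and in none of the 17 genes do the groups overlap.

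The gene lists that follow were fixed before the data were examined. For each, the members that rose and fell are given over all tested genes, then adjusted over the list alone, then as the range over the fits with 1 library left out. Of 31 lists with at least 5 tested members, 12 were called by camera with its preset correlation of 0.01, all upward, and 1 with an estimated correlation. For some of these 12 the estimate lay below 0.01: NF-kB (−0.027), TNF superfamily receptors (−0.0068), cytokines (0.0015), inflammation-associated fibroblast genes (−0.042) and AP-1 genes (−0.0062). Their weaker calls with an estimated correlation therefore do not come from a correlation of their members above the preset. Splits of the libraries that mix the treatments gave 3 to 13 called lists. Each such split holds more libraries of 1 treatment on either side, so part of the treatment difference remains in it. These splits therefore do not measure false calls by camera. The counts of called members carry the description here, and the camera p-value is given beside them. The directional test fry, which compares a list with no other genes, is given where it called a list that camera did not.

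The list of NF-kB regulators and feedback genes rose broadly. Of 28 tested members 22 rose and 0 fell, 23 and 0 adjusted over the list alone, and 20 to 21 and 0 to 1 with 1 library left out. Its median log2 fold change was 0.90, with a camera adjusted p of 1.6e-16, and 0.019 with an estimated correlation. After BIRC3, the largest increases were in TNFAIP3 (3.76 ± 0.10), which encodes the NF-kB inhibitor A20, and in RELB (3.005 ± 0.10) and NFKB2 (2.85 ± 0.06), the partners of the non-canonical NF-kB dimer. NFKB2 went from 507 ± 11.3 to 3672 ± 143 and RELB from 151 ± 16.9 to 1213 ± 68.2.

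Among TNF superfamily receptors, 9 of 19 rose and 2 fell, 9 and 2 adjusted over the list alone, and 8 to 10 and 1 to 3 with 1 library left out. The median was 0.62 and the camera adjusted p 0.0016, but 0.11 with an estimated correlation. TNFRSF9 was listed at 0 in all 3 vehicle libraries and at 20.6 ± 4.89 under TWEAK. TNFRSF1B, the TNF receptor 2 gene, rose by 2.10 ± 0.12, the osteoprotegerin gene TNFRSF11B by 1.86 ± 0.06 and RELT by 1.597 ± 0.17.

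Chemokines and cytokines had the highest medians of the 31 lists. Of 12 tested chemokines 7 rose and 1 fell, 7 and 1 adjusted over the list alone, and 6 to 7 and 1 to 1 with 1 library left out. The chemokine median was 1.6001. Setting the members near 0 reads at their bound could not move it, since they lie above it either way. The camera adjusted p was 0.0012, but 0.20 with an estimated correlation. Among genes with a mean of at least 50 the median was 0.79 and the camera adjusted p 0.19. CXCL10, a ligand of CXCR3, rose from 3.66 ± 2.05 to 59.5 ± 10.5 (3.77 ± 0.38). CXCL11 was listed at 0.347 ± 0.601 in vehicle and 30.9 ± 4.30 under TWEAK, a ratio of 93.0 with a counting interval of 16.3 to 3714. CXCL5 was listed at 0.976 ± 0.980 and 27.995 ± 4.52, a ratio of 28.3 with an interval of 9.36 to 140.1. CCL5 was listed at 0 in all 3 vehicle libraries and at 21.4 ± 10.1 under TWEAK. Chosen after their values were seen, the monocyte chemoattractant CCL2 rose by 2.67 and CXCL12, a ligand of ACKR3, fell by 0.82 on the log2 scale.

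Of 18 cytokines and colony-stimulating factors 11 rose and 1 fell, 11 and 1 adjusted over the list alone, and 11 to 11 and 0 to 1 with 1 library left out. The median was 1.31 and the camera adjusted p 2.6e-07, but 0.062 with an estimated correlation. IL34, a ligand of the CSF1 receptor, went from 13.8 ± 6.98 to 420 ± 63.4 and IL32 from 159 ± 18.5 to 2977 ± 510. IL6 rose from 33.0 ± 6.51 to 299.5 ± 52.0 (3.15 ± 0.19), and IL1B from 6.96 ± 4.84 to 93.9 ± 15.1 (3.80 ± 0.49).

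Of 19 cytokine receptors and decoys 10 rose and 3 fell, 11 and 5 adjusted over the list alone, and 10 to 11 and 1 to 3 with 1 library left out. The median was 0.55 and the camera adjusted p 0.0018, but 0.16 with an estimated correlation. IL7R rose by 3.36 ± 0.25, the interferon receptor genes IFNAR2 by 1.75 ± 0.09 and IFNGR2 by 1.246 ± 0.07, and LIFR by 1.22 ± 0.16.

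Leukocyte adhesion molecules moved in both directions. Of 16 tested members 5 rose and 5 fell, 6 and 5 adjusted over the list alone, and 4 to 5 and 3 to 5 with 1 library left out, with a median of 0.02, a camera adjusted p of 0.63 and an upward call by fry (0.0058). The integrin ligands ICAM1 and VCAM1 rose, from 1026 ± 34.7 to 5542 ± 266 (2.43 ± 0.07) and from 3613 ± 1193 to 16224 ± 3005 (2.20 ± 0.21). ALCAM fell by 0.96 ± 0.10 and ICAM4 by 1.07 ± 0.24. The ICAM4 call was lost without vehicle replicate 1 (adjusted p = 0.057) or vehicle replicate 2 (0.056), over a range of 0.0049 to 0.057.

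**Figure D3:**
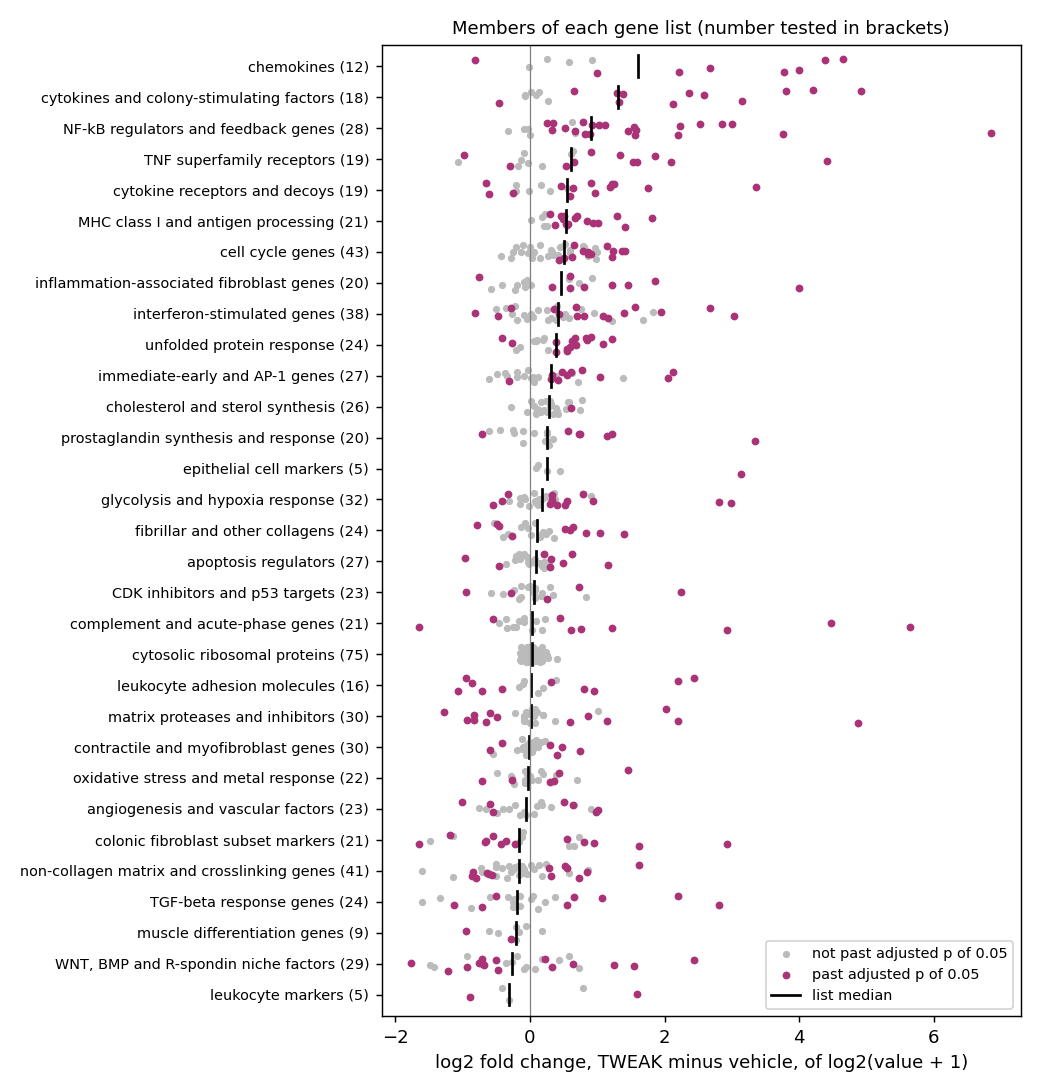
Log2 fold changes (x axis, TWEAK minus vehicle) of the tested members of each list with at least 5 of them, ordered by median, with 1 point per gene, purple where the limma adjusted p is under 0.05 and grey otherwise, and a black bar at the list median. The medians run from −0.32 for leukocyte markers to 1.6001 for chemokines, and 22 of 28 NF-kB genes are purple and to the right of 0.

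MHC class I and antigen processing genes rose together. Of 21 tested members 16 rose and 0 fell, 18 and 0 adjusted over the list alone, and 14 to 18 and 0 to 0 with 1 library left out. The median was 0.53 and the camera adjusted p 3.4e-11, but 0.079 with an estimated correlation. PSME2, a proteasome activator subunit, rose from 742 ± 40.6 to 2604 ± 204 (1.81 ± 0.08), the peptide transporter gene TAP1 from 1381 ± 39.9 to 3668 ± 87.0 (1.41 ± 0.06), HLA-F by 1.29 ± 0.15 and the immunoproteasome subunit gene PSMB9 by 1.009 ± 0.11. HLA genes resemble each other, so how reads were divided among them is uncertain.

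Interferon-stimulated genes responded unevenly. Of 38 tested members 12 rose and 3 fell, 16 and 6 adjusted over the list alone, and 7 to 14 and 1 to 4 with 1 library left out, the lowest number of increases being without TWEAK replicate 2. Without both libraries numbered 3, 22 rose and 5 fell. The median was 0.42 and the camera adjusted p 0.0064, but 0.53 with an estimated correlation and 0.080 among genes with a mean of at least 50. The antiviral oligoadenylate synthetase genes OAS1 (3.03 ± 0.64), OAS2 (2.68 ± 0.53) and OAS3 (1.56 ± 0.21) rose, from means of 4.41, 12.4 and 83.9 to 35.2, 77.2 and 257. CMPK2 rose by 1.94 ± 0.44. Without TWEAK replicate 2 the calls of OAS1 (adjusted p = 0.053) and CMPK2 (0.068) were lost, over ranges of 5.6e-05 to 0.053 and 0.0020 to 0.068. The members that fell, all named here because they were few, were IFIT1 (−0.82 ± 0.26), IFITM2 (−0.48 ± 0.08) and STAT2 (−0.28 ± 0.07). Only 1 member of the list fell without vehicle replicate 2, and only 1 without TWEAK replicate 1, so most of these calls were lost there.

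Of 21 complement and acute-phase genes 7 rose and 2 fell, 7 and 3 adjusted over the list alone, and 5 to 7 and 2 to 3 with 1 library left out, with a median of 0.04 and a camera adjusted p of 0.44. C3, the central complement component, rose from 148 ± 58.1 to 1087 ± 137 (2.93 ± 0.23), while C7 fell. SAA2 was listed at 0 in all 3 vehicle libraries and at 24.3 ± 16.3 under TWEAK. SAA1 and SAA2 are near-identical, so the division of reads between them is uncertain.

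Of 20 inflammation-associated fibroblast genes 8 rose and 1 fell, 8 and 1 adjusted over the list alone, and 7 to 9 and 1 to 2 with 1 library left out. The median was 0.46 and the camera adjusted p 0.014, but 0.16 with an estimated correlation. Beside CXCL5 and TNFRSF11B, the mitochondrial superoxide dismutase gene SOD2 rose from 3071 ± 363 to 8397 ± 1176 (1.45 ± 0.12) and the activin A subunit gene INHBA from 101 ± 21.9 to 234 ± 16.8 (1.22 ± 0.16). IL11 (0.01), MMP1 (−0.07), MMP3 (−0.22) and FAP (−0.20), chosen after their values were seen, did not pass the test.

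Of 20 prostaglandin genes 6 rose and 1 fell, 7 and 2 adjusted over the list alone, and 5 to 6 and 1 to 2 with 1 library left out. The median was 0.26 and the camera adjusted p 0.11, or 0.40 with an estimated correlation, but 0.042 with no filter on low values and 0.013 (upward) by fry. The phospholipase gene PLA2G4C rose from 35.2 ± 11.03 to 359 ± 64.5 (3.34 ± 0.24), the prostaglandin receptor genes PTGER4 by 1.22 ± 0.23 and PTGIR by 1.14 ± 0.18, and the prostaglandin E synthase gene PTGES by 0.74 ± 0.09. Among genes chosen after their values were seen, the cyclooxygenase genes PTGS2 (−0.10) and PTGS1 (0.26) did not pass. The member that fell was the receptor gene PTGER2 (−0.71).

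Of 24 collagens 6 rose and 4 fell, 6 and 4 adjusted over the list alone, and 5 to 7 and 3 to 5 with 1 library left out, with a median of 0.11, a camera adjusted p of 0.63 and an upward call by fry (0.0095). The basement membrane collagen COL4A1 rose from 25590 ± 1352 to 52399 ± 1866 (1.03 ± 0.08), COL13A1 rose by 1.40 ± 0.17, and COL8A1 fell by 0.78 ± 0.12. COL4A4 rose by 0.83 ± 0.23, a call lost without vehicle replicate 1 (adjusted p = 0.10), vehicle replicate 2 (0.071), TWEAK replicate 2 (0.11) or TWEAK replicate 3 (0.078), and without the variance trend (0.061), over a range of 0.0036 to 0.11. Fibrillar collagens, chosen after their values were seen, were mixed. COL1A1 (−0.33), COL1A2 (−0.13) and COL3A1 (0.01) did not pass, while COL5A2 rose (0.52) and COL11A1 (−0.45) and COL5A1 (−0.27) fell.

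Of 41 other matrix and crosslinking genes 7 rose and 6 fell, 8 and 7 adjusted over the list alone, and 4 to 10 and 5 to 11 with 1 library left out, with a median of −0.17 and a camera adjusted p of 0.26. The lowest number of increases was without vehicle replicate 1 and the highest number of decreases without TWEAK replicate 3, and without both libraries numbered 3 the numbers were 12 and 18. The lysyl hydroxylase gene PLOD2 rose by 0.85 ± 0.14, and the proteoglycan gene VCAN (−0.86 ± 0.18) and the nidogen gene NID2 (−0.84 ± 0.14) fell. POSTN rose by 1.61 ± 0.40, a call lost without vehicle replicate 1 (adjusted p = 0.070) or vehicle replicate 2 (0.067), and without the variance trend (0.058), over a range of 2.9e-06 to 0.070.

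Of 30 matrix proteases and inhibitors 6 rose and 7 fell, 7 and 7 adjusted over the list alone, and 6 to 9 and 4 to 7 with 1 library left out, with a median of 0.02, a camera adjusted p of 0.63 and an upward call by fry (0.041). Beside CTSS, ADAMTS4 rose by 2.02 ± 0.31, while ADAMTS9 fell by 1.27 ± 0.21.

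Of 30 contractile and myofibroblast genes 4 rose and 2 fell, 4 and 2 adjusted over the list alone, and 2 to 5 and 2 to 2 with 1 library left out. The median was −0.02, the mean 0.01 and the camera direction upward, with an adjusted p of 0.83. The smooth muscle myosin gene MYH11 rose by 0.75 ± 0.11 and TAGLN2 by 0.48 ± 0.08, while LMOD1 fell by 0.59 ± 0.07 and SMTN by 0.41 ± 0.06. ACTA2, the α smooth muscle actin gene, chosen after its value was seen, had a log2 fold change of 0.04 and did not pass.

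Of 24 TGF-β response genes 5 rose and 3 fell, 7 and 6 adjusted over the list alone, and 3 to 6 and 2 to 4 with 1 library left out, and without both libraries numbered 3 the numbers were 7 and 9. The median was −0.19 and the camera adjusted p 0.63. The transcription factor gene BHLHE40 rose from 174 ± 11.7 to 1225 ± 125 (2.81 ± 0.10), and the BMP pathway inhibitor SMAD6 fell from 808 ± 43.3 to 368 ± 26.4 (−1.13 ± 0.09). TGFB2 rose by 1.07 ± 0.24, a call lost without vehicle replicate 2 (adjusted p = 0.051), over a range of 6.8e-07 to 0.051.

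Of 29 WNT, BMP and R-spondin niche factors 6 rose and 10 fell, 7 and 12 adjusted over the list alone, and 3 to 8 and 9 to 10 with 1 library left out. Only 3 rose without vehicle replicate 2, TWEAK replicate 1 or TWEAK replicate 2. The median was −0.27 and the camera adjusted p 0.26. Beside RSPO2, which fell, the EGF family gene HBEGF rose from 81.5 ± 5.804 to 443 ± 25.7 (2.43 ± 0.11) and BMP2 from 571 ± 52.97 to 1359 ± 115 (1.2495 ± 0.10). The WNT antagonist gene DKK1 rose by 1.55 ± 0.42, a call lost without vehicle replicate 1 (adjusted p = 0.097), vehicle replicate 2 (0.10), TWEAK replicate 1 (0.057), TWEAK replicate 2 (0.060) or TWEAK replicate 3 (0.078), and without the variance trend (0.076), over a range of 1.0e-07 to 0.10.

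Of 21 colonic fibroblast subset markers 5 rose and 8 fell, 7 and 8 adjusted over the list alone, and 4 to 7 and 3 to 7 with 1 library left out. The median was −0.16, the mean 0.01 and the camera direction downward, with an adjusted p of 0.63. C3 and POSTN rose and C7 fell, as above. NSG1 fell by 1.19 ± 0.30, a call lost in 4 of the 6 fits with 1 library left out, those without vehicle replicate 1 (adjusted p = 0.080), vehicle replicate 2 (0.082), TWEAK replicate 2 (0.052) or TWEAK replicate 3 (0.053), and without the variance trend (0.065), over a range of 1.8e-08 to 0.082. Of 23 angiogenesis and vascular factors 4 rose and 3 fell, 4 and 3 adjusted over the list alone, and 3 to 6 and 3 to 4 with 1 library left out, with a median of −0.07, a mean of 0.01 and an upward camera direction at an adjusted p of 0.70. VEGFC rose by 1.008 ± 0.09 and FGF2 by 0.64 ± 0.06, and the endothelin gene EDN1 fell by 1.003 ± 0.14. TFPI2 rose by 0.97 ± 0.25, a call lost without TWEAK replicate 1 (adjusted p = 0.088) or TWEAK replicate 2 (0.077), and without the variance trend (0.066), over a range of 9.1e-08 to 0.088.

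Of 43 tested cell cycle genes 13 rose and 0 fell, 18 and 0 adjusted over the list alone, and 5 to 11 and 0 to 0 with 1 library left out. The number was 7 without vehicle replicate 1, 5 without vehicle replicate 2, 6 without TWEAK replicate 1 and 8 without TWEAK replicate 2. The median was 0.51 and the camera adjusted p 0.00064, but 0.20 with an estimated correlation and 0.093 among genes with a mean of at least 50. The separase gene ESPL1 rose from 18.2 ± 2.07 to 51.7 ± 17.4 (1.41 ± 0.27) and the survivin gene BIRC5 from 15.2 ± 1.80 to 40.7 ± 5.67 (1.36 ± 0.24). The proliferation marker MKI67 rose from 20.1 ± 6.53 to 50.7 ± 24.5 (1.24 ± 0.37) and CDK1 from 11.6 ± 4.23 to 27.2 ± 1.47 (1.22 ± 0.32). The MKI67 call was lost without vehicle replicate 1 (adjusted p = 0.0996), vehicle replicate 2 (0.12), TWEAK replicate 1 (0.072) or TWEAK replicate 3 (0.088), with no filter (0.054) and without the variance trend (0.065), over a range of 0.0028 to 0.12. The CDK1 call was lost without vehicle replicate 2 (adjusted p = 0.071), vehicle replicate 3 (0.057), TWEAK replicate 1 (0.083) or TWEAK replicate 2 (0.074), over a range of 0.014 to 0.083.

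Of 23 CDK inhibitors and p53 targets 3 rose and 2 fell, 3 and 2 adjusted over the list alone, and 2 to 3 and 1 to 4 with 1 library left out, with a median of 0.06, a camera adjusted p of 0.64 and an upward call by fry (0.019). The stress gene GADD45A rose from 1388 ± 68.7 to 6580 ± 900 (2.24 ± 0.10) and PLK3 by 0.72 ± 0.11, while the CDK inhibitor gene CDKN1C fell by 0.95 ± 0.17. TP53INP1 fell by 0.28 ± 0.07, a call lost without vehicle replicate 1 (adjusted p = 0.060) or TWEAK replicate 2 (0.092), and without the variance trend (0.057), over a range of 0.0054 to 0.092. Of 27 apoptosis regulators 6 rose and 2 fell, 9 and 3 adjusted over the list alone, and 3 to 6 and 1 to 2 with 1 library left out, with a median of 0.08, a camera adjusted p of 0.26 and an upward call by fry (0.013). CFLAR, an inhibitor of caspase-8 activation, rose by 1.15 ± 0.10, BID by 0.62 ± 0.07 and RIPK2 by 0.49 ± 0.10. BMF fell by 0.97 ± 0.29, a call lost without vehicle replicate 2 (adjusted p = 0.079), vehicle replicate 3 (0.078), TWEAK replicate 1 (0.12) or TWEAK replicate 2 (0.13), and without the variance trend (0.092), over a range of 1.9e-05 to 0.13.

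Of 24 unfolded protein response genes 13 rose and 2 fell, 13 and 2 adjusted over the list alone, and 11 to 14 and 0 to 2 with 1 library left out. The median was 0.38 and the camera adjusted p 5.8e-05, but 0.11 with an estimated correlation. The chaperone gene HYOU1 rose from 1658 ± 129 to 3532 ± 218 (1.09 ± 0.08), the stress sensor gene ERN1 by 1.21 ± 0.13, DNAJB9 by 0.90 ± 0.15 and MANF by 0.84 ± 0.09. The members that fell, DDIT3 (−0.42) and ATF4 (−0.27), chosen after their values were seen, encode transcription factors of the PERK branch. Both calls were lost without vehicle replicate 1, vehicle replicate 2, TWEAK replicate 1 or TWEAK replicate 2.

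Of 27 immediate-early and AP-1 genes 10 rose and 1 fell, 10 and 3 adjusted over the list alone, and 6 to 11 and 1 to 2 with 1 library left out, with 6 increases without vehicle replicate 1 or TWEAK replicate 2. The median was 0.31 and the camera adjusted p 0.022, but 0.16 with an estimated correlation and 0.056 with GC and length trends removed. JUNB rose from 434 ± 111 to 1878 ± 298 (2.13 ± 0.18) and FOSL1 from 162 ± 5.47 to 675 ± 60.9 (2.05 ± 0.09), both AP-1 subunits, and MAFF rose by 1.05 ± 0.10 and KLF4 by 0.77 ± 0.15.

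Of 32 glycolysis and hypoxia genes 10 rose and 3 fell, 13 and 3 adjusted over the list alone, and 7 to 13 and 1 to 3 with 1 library left out, and without both libraries numbered 3 the numbers were 15 and 4. The median was 0.17 and the camera adjusted p 0.0078, but 0.34 with an estimated correlation. Pyruvate kinase PKM rose from 11516 ± 1066 to 22044 ± 889 (0.94 ± 0.09), lactate dehydrogenase LDHA by 0.79 ± 0.11 and the prolyl hydroxylase gene EGLN3 by 2.98 ± 0.59. Of 22 oxidative stress and metal genes 4 rose and 2 fell, 4 and 2 adjusted over the list alone, and 3 to 5 and 1 to 2 with 1 library left out, with a median of −0.02, a mean of 0.07 and an upward camera direction at an adjusted p of 0.69. Beside SOD2, the zinc and iron transporter gene SLC39A14 rose by 0.36 ± 0.07 and catalase, CAT, fell by 0.72 ± 0.09. Ferritin heavy chain FTH1, which has many processed pseudogenes, rose by 0.43 ± 0.11, a call lost without vehicle replicate 1 (adjusted p = 0.083) or vehicle replicate 2 (0.065), over a range of 0.00014 to 0.083.

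Cholesterol and sterol synthesis genes depended on the replicate 3 libraries. Over all 6 libraries 1 of 26 members rose and 0 fell, 0 and 0 adjusted over the list alone, and 0 to 2 and 0 to 0 with 1 library left out, with a median of 0.28 and a camera adjusted p of 0.13. The member was SREBF2 (0.61 ± 0.15), the transcription factor of the pathway, and its call was lost without TWEAK replicate 1 (adjusted p = 0.082) or TWEAK replicate 2 (0.081), and without the variance trend (0.062), over a range of 4.3e-07 to 0.082. Without both libraries numbered 3, 14 members rose and 1 fell, with a camera adjusted p of 0.00073 at the preset correlation. The camera call at that setting also appeared without vehicle replicate 1 (adjusted p = 0.014), vehicle replicate 2 (0.0081) or TWEAK replicate 3 (0.0016). Over all 6 libraries the estimated correlation of this list was 0.97, far above the preset 0.01, and the camera adjusted p with it was 0.81. The joint shift of the replicate 3 libraries enters that estimate. No correlation was estimated for the fits that gave these calls, so whether they would hold with one was not tested. TWEAK libraries were higher than the vehicle library of the same number for 22, 22 and 24 of the 26 genes in pairs 1, 2 and 3. In both replicate 3 libraries the list was lower than in the other libraries of the same group, by medians of −1.05 in vehicle and −0.79 under TWEAK on the log2 scale, with 25 of 26 members lower (limma, group as a covariate).

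**Figure D4:**
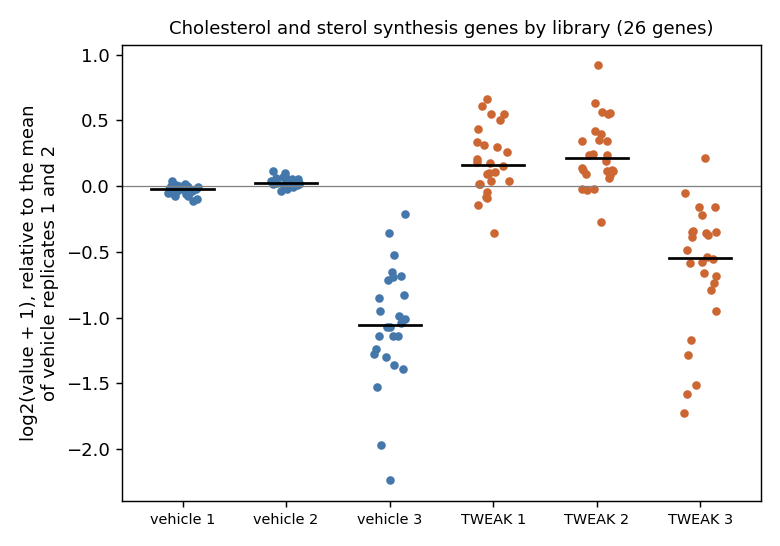
Log2(value + 1) of 26 cholesterol and sterol synthesis genes in each library, relative to each gene's mean over vehicle replicates 1 and 2 (y axis), with 1 point per gene, blue for vehicle and orange for TWEAK, and a bar at the median. The medians lie at 0.16 and 0.21 in TWEAK replicates 1 and 2, at −1.05 in vehicle replicate 3 and at −0.54 in TWEAK replicate 3.

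The 75 cytosolic ribosomal protein genes gave 0 calls by limma, over all genes and adjusted over the list alone, and 0 to 5 increases and 0 to 0 decreases with 1 library left out, with a median of 0.03 and a camera adjusted p of 0.62. At an unadjusted p under 0.05, 3 members passed. The most abundant members, RPLP0 (−0.06 ± 0.13) and RPL3 (0.08 ± 0.11), did not pass. Without TWEAK replicate 3, 5 members rose and the camera adjusted p was 0.0054 at the preset correlation. The estimated correlation of this list was 0.67, and the adjusted p with it, over all 6 libraries, was 0.92. Without both libraries numbered 3, 14 rose and 1 fell. Of 9 muscle differentiation genes 0 rose and 2 fell, 0 and 2 adjusted over the list alone, and 0 to 0 and 0 to 1 with 1 library left out, with a camera adjusted p of 0.086 and a downward call by fry (0.018). TNNT2 fell by 0.95 ± 0.21, a call lost without vehicle replicate 1 (adjusted p = 0.054) or vehicle replicate 2 (0.055), over a range of 2.8e-06 to 0.055. MEF2D fell by 0.29 ± 0.09, a call lost without any 1 of the 6 libraries (adjusted p = 0.059 without vehicle replicate 1 to 0.13 without TWEAK replicate 2), without both libraries numbered 3 (0.051), with no filter (0.054) and without the variance trend (0.095), over a range of 0.019 to 0.13.

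Markers of other cell types were few. Of 5 tested epithelial markers 1 rose and 0 fell, 1 and 0 adjusted over the list alone, and 1 to 2 and 0 to 0 with 1 library left out, with a camera adjusted p of 0.19 and an upward call by fry (0.019). The member was CDX1, an intestinal transcription factor, at 1.69 ± 1.24 in vehicle and 28.4 ± 27.4 under TWEAK, where TWEAK replicate 3 alone held 59.9. Of 5 leukocyte markers 1 rose and 1 fell, 1 and 1 adjusted over the list alone, and 0 to 1 and 1 to 1 with 1 library left out, with a median of −0.32, a mean of 0.15 and a camera adjusted p of 0.63. CD14 rose from 53.6 ± 31.4 to 163 ± 91.2 (1.59 ± 0.44), a call lost without vehicle replicate 1 (adjusted p = 0.10), vehicle replicate 2 (0.10), TWEAK replicate 2 (0.065) or TWEAK replicate 3 (0.071), and without the variance trend (0.076), over a range of 2.1e-05 to 0.10. The receptor tyrosine kinase gene KIT fell from 2498 ± 42.0 to 1361 ± 177 (−0.88 ± 0.10). Of 4 tested endothelial markers 0 rose and 1 fell, 0 and 1 adjusted over the list alone, and 0 to 0 and 0 to 1 with 1 library left out. TEK fell by 0.44 ± 0.13, a call lost without TWEAK replicate 1 (adjusted p = 0.11) or TWEAK replicate 2 (0.11), and without the variance trend (0.085), over a range of 4.3e-05 to 0.11. Of 4 tested glia and neuron markers 1 rose and 0 fell, 1 and 0 adjusted over the list alone, and 0 to 1 and 0 to 0 with 1 library left out. TUBB3 rose by 0.30 ± 0.06, a call lost without vehicle replicate 1 (adjusted p = 0.055) or TWEAK replicate 2 (0.059), over a range of 0.0014 to 0.059. Both lists were too short for camera, and no member of the mitochondrial list was matched.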

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

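The fits without both libraries numbered 3 and with GC and length trends removed were chosen after the data were seen. The number of changed genes stayed within 1.5 times of 3278 under other pseudocounts, filters, scalings and without the variance trend (2667 to 3293), though quantile normalization gave more decreases (1689) than increases (1598), and the scalings moved the median of all genes by less than 0.1. Leaving out 1 library gave 2029 to 3282 changed genes, 1115 to 1766 increases and 913 to 1516 decreases. The totals were 2029 to 2245 without a library numbered 1 or 2. They were 3282 without vehicle replicate 3 and 3068 without TWEAK replicate 3. Without both libraries numbered 3 the count was 5074, with 2688 increases and 2386 decreases. Changes of at least 2-fold numbered 531 and ranged from 354, among genes with a mean of at least 50 of which fewer were tested, to 632 with no filter. With the replicate number as a block, 4927 genes changed, 2512 up and 2415 down, and all 3278 genes of the fit without the block were among them. Deviations of same-numbered libraries had correlations across genes of 0.02, 0.13 and 0.26 for replicates 1, 2 and 3, and vehicle replicate 1 correlated best with TWEAK replicate 2 (0.20). Since deviations are taken from the group mean, a shift shared by the replicate 3 libraries also ties replicates 1 and 2 together. The 0.20 therefore does not decide the pairing. The labels do not pair the numbers, so the block stayed an alternative, and the shift of replicate 3 remained in the error of the main fit. The block also called the cholesterol and sterol synthesis list with the preset correlation (camera adjusted p = 5.1e-05), against 0.13 without the block, and 0.81 without the block with the estimated correlation of 0.97.

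TNFRSF12A and TNFSF12 kept their direction and their side of the threshold under every alternative. Of 1972 values of the 117 named genes under the alternatives, 1901 kept direction and side of the threshold, 71 lost the call, of them 56 with 1 library left out, and 0 reversed. Of the 12 lists called by camera, 1 was called with an estimated correlation. By fry, which compares a list with no other genes, 20 of 31 lists moved on balance one way and 29 changed in either direction. Of 587 list results 15 lost a call, 15 gained one and 0 reversed, and 11 results called in neither fit changed sign. The share of the first component, 53.6%, was 57.6% with a pseudocount of 5, 38.7% with no filter, 60.7% with a mean of at least 50, 56.9% with GC and length trends removed, 71.6% without both libraries numbered 3 and 54.1% to 60.2% with 1 library left out. Some of these fits also hold other numbers of genes or libraries, and the cause of the differences was not tested. The share was 59.3% without vehicle replicate 3 and 60.2% without TWEAK replicate 3, against 54.1% to 56.0% without any other library. The replicate 3 libraries are those that the second component set apart. Tests on counts by edgeR and DESeq2 were not run, since whole reads were not recovered. Depth limits genes such as CCL5, TNFRSF9 and SAA2, listed at 0 in vehicle, for which no fold is given.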

Other observations

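Tests of ribosomal RNA, of the interferon response, of noise near the detection floor and of other splits for 2-fold changes and lists were chosen after the results were seen, as was the fit without both libraries numbered 3. Within each group, replicate 3 stood apart in named genes. With group as a covariate, 994 genes were higher and 941 lower in the replicate 3 libraries than in replicates 1 and 2 (limma, adjusted p under 0.05). The elastin gene ELN (log2 difference 1.61), the small proteoglycan gene ASPN (2.32), ANGPTL4 (2.99), PDK4 (1.81) and the cholesterol exporter gene ABCA1 (1.33) were higher. The sterol and lipid synthesis genes ACAT2 (−1.75), SCD (−1.40) and HMGCS1 (−1.30) were lower. By list, 25 of 26 cholesterol and sterol synthesis genes, 34 of 75 ribosomal protein genes and 12 of 30 contractile genes were lower. Of 41 matrix genes 21 were higher and 4 lower, and of 24 TGF-β response genes 13 were higher. The cholesterol list had a camera adjusted p of 7.0e-35, but 0.19 with an estimated correlation. These genes were picked after their values were seen.

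The joint deviation of both replicate 3 libraries had a correlation of 0.26 across genes. Over the genes with a GC value the correlation was 0.278, and removing GC and length trends left 101.0% of it (0.281), and 2 of 2 replicate 3 libraries had ribosomal RNA shares inside the range of the 4 others, which argues against both as its source. For a different growth state, the cell cycle list deviated by a median of −0.017 in vehicle (bootstrap interval −0.28 to 0.14) and 0.20 under TWEAK (0.071 to 0.31). Opposite signs had been set beforehand as the result that goes against this explanation. It was still kept open, since the interval in vehicle spans 0 and leaves that sign uncertain. That condition on the interval was not part of the criterion set beforehand. A candidate explanation is that more lipid was available to these cultures. The 13 lipid response genes not looked at before had median deviations of 0.42 in vehicle (interval 0.088 to 0.48) and 0.23 under TWEAK (0.033 to 0.47). However, MYLIP and IMPA2 were lower in both, and ABCG1 deviated by 0.48 in vehicle and −0.15 under TWEAK. The bootstrap intervals resample genes, not libraries, so they do not measure the spread between cultures. The design names no biological difference between replicate numbers. A difference in culture day or in the length of the serum-free period cannot be separated from more available lipid here. The shares of low values near whole multiples of the step were 69.4% and 70.6% in vehicle and TWEAK replicate 3. The other libraries had 75.5% to 77.7%, and a technical source of the joint deviation, other than those above, was not tested.

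The 3278 genes that differed between TWEAK and vehicle were compared with other splits of the libraries. Of the 10 splits of 6 libraries into 3 and 3, 1 gave as many calls, the real one, and the highest of the others gave 2, and for 2-fold changes 1 split gave 531, with 2 as the highest of the others, but 10 splits are too few for a share under 0.05. For called lists, 2 of the 10 splits gave 12 or more, and the highest of the others, which set vehicle replicates 1 and 2 and TWEAK replicate 2 against the rest, gave 13. In every split but the real one, part of the treatment difference remains and the rest adds to the error. Their counts of genes and lists therefore do not show what chance alone gives. Removing GC and length trends left 96.9% of the called genes with a GC value called in the same direction, which argues against those trends as the whole source. The treatment is the only difference between the groups that the design names. An unnamed difference cannot be separated from it here, since the labels do not say that the replicates came from separate cultures.

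Interferon-stimulated genes rose in part and fell in part under TWEAK. Of the 29 members with a mean of at least 50, 12 were called in a fit of such genes alone, 9 up and 3 down, which argues against noise near the detection floor for these members, though camera no longer called the list there (adjusted p = 0.080, over a range of 0.00027 to 0.53). Of the 3 called members below a mean of 50, 1, OAS2, stayed called whichever library was left out, which goes against such noise. OAS1 and CMPK2 lost their calls without TWEAK replicate 2, with log2 fold changes of 2.71 ± 0.76 and 1.77 ± 0.54 there against 3.03 ± 0.64 and 1.94 ± 0.44 in all libraries, so the lost calls do not support noise either, and for these members it stays open because so few reads decide little. IFIT1, IFIT2, IFIT3, IFIT5, ISG15, IFI6 and IFI27, a choice that left out IFI35 (0.016), had a median log2 fold change of 0.31 (bootstrap interval −0.085 to 0.52). The median was 1.75 for OAS1, OAS2, OAS3, IFIH1, CMPK2 and MX1. These were chosen after their values were seen and all are called members that rose, so their higher median was fixed by the choice. The contrast is therefore no test of an uneven response. The median of 0.31 lies between the bounds set for a general interferon response. Such a response, weak or uneven at 24 h, may or may not be part of the treatment's effect, and these data leave it open.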
